A study of Mus musculus with 9 samples.

How the data were processed

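The deposited table holds 1 log2 value per transcript cluster and array, made by the authors with robust multiarray average (RMA) in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalizes between arrays and sums the probes of a cluster, and the version used is not given in the sources used here. The labels name the Mouse Exon 1.0 ST array, while the cluster identifiers in the deposited table are of the transcript cluster type of later whole-transcript arrays, and the values were used as deposited. All 9 sample columns were used, and 0 were left out. Of 21072 clusters, 6935 held 9 distinct values, 4412 held fewer than 6 and 258 held 1 value on all arrays. These tied values were kept, and clusters with fewer than 6 distinct values made up 1, 0 and 0 of the calls in the comparisons of wild type with empty vector, R396Q with empty vector and R396Q with wild type.

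Symbols came from the array annotation. The gene identifiers of 18236 clusters with 1 symbol were matched to a reference gene table, which brought 418 symbols up to date. In all, 18992 clusters had 1 symbol, 1390 had several and 690 had none, and only clusters with 1 symbol were used for genes and lists. Of 18797 distinct symbols, 171 had several clusters, and the one with the highest mean over the 9 arrays was used. No genomic positions are given, since the genome build is not named in the sources used here.

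Each cluster was tested with limma 3.58.1 in R 4.3.3 (linear model over all 9 arrays with 1 mean per group, empirical Bayes, 6 residual and 0.956 prior degrees of freedom). The tests were 2-sided, and p was adjusted by the Benjamini-Hochberg method over all 21072 clusters within each comparison, with 0.05 as the threshold. A moderated F-test covered any difference among the 3 groups. Expression was not filtered for these tests, while principal components were taken over 14750 of the 21072 clusters. The groups, the tests, the 20 gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. Leaving out clusters with fewer than 6 distinct values, with and without the replicate block, was added after seeing the data.

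The 20 lists hold hematopoietic stem cell, blood transcription factor, megakaryocyte, erythroid, mast cell, basophil and eosinophil, neutrophil, monocyte and macrophage, dendritic cell, lymphoid, S phase, G2 and M phase, cell cycle inhibitor, p53 response, interferon response, stress, cytokine and growth factor receptor, ribosomal protein, heme and iron, and stromal and endothelial genes. They were written from general knowledge and some genes stand in more than 1 list. The cell cycle inhibitor list also holds genes of quiescence, such as Foxo3 and Txnip, so not all its members are inhibitors. Of 610 entries, 529 were measured, 39 fell in a cluster with several symbols and 42 had no cluster with the symbol. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 60 tests (20 lists in 3 comparisons), and again with an estimated correlation and with fry, whose test asks whether the genes of a list move, on balance, in one direction without comparing them with other genes. A list's rise or fall is the direction of the camera test.

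Named genes were Gata2, then per comparison the 12 largest rises and 12 largest falls among clusters with 1 symbol that passed the test and whose groups did not overlap, leaving out symbols of predicted or unstudied genes, and then for each list up to 4 called members with the smallest p. Where a list had fewer than 2 called members, up to 2 with the smallest p are given as values. The text prints a part of these.

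Replicate numbers were tested for pairing by correlating each array's deviations from its group mean. The 9 pairs of arrays with the same number in different groups had r of 0.451 to 0.693, and pairs with different numbers -0.537 to -0.0900. For 9 of 9 arrays the best match in each other group had the same number. The labels do not say what arrays with the same number share. The number was therefore added as a block in an alternative fit, and list medians were also taken within each number. Whether the 3 samples of a group came from separate mice or cultures is not stated, so p measures only the spread between these samples. The number of arrays, 3 per group, limits the precision.

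Other settings tried were the replicate block, fits on only the groups compared, limma with trend and robust options, array weights, subtraction of each array's median, quantile normalization, leaving out the dimmest 30% or 50% of clusters, 1 cluster per symbol, the mean of a symbol's clusters, and leaving out each array in turn. The median change over all clusters moved by less than 0.1 on the log2 scale under each scaling, from -0.01, -0.01 and 0.00 as deposited to -0.03, 0.02 and 0.05 after median subtraction and 0.00, 0.01 and 0.01 after quantile normalization, for wild type with empty vector, R396Q with empty vector and R396Q with wild type in turn.

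The pipeline was tested on simulated data of 21072 clusters with 100 changed clusters per size and comparison. Changes of 1 on the log2 scale were recovered in 72%, 76% and 65% of cases in the 3 comparisons and changes of 2 in 93%, 90% and 92%, and 7.82%, 3.49% and 8.72% of calls were false. The 1 list shifted by construction was called in each comparison, and of the others among the 20 lists 1, 0 and 0 were called. The simulated noise was independent between genes, so this does not show how often camera calls lists whose genes are correlated. Other splits of the real arrays called up to 13, 10 and 12 lists. Shared controls were simulated 100 times with unchanged groups. Intervals of median ratios came from 10000 bootstrap draws of the genes of a list, so they hold no spread between arrays. Figures were drawn with matplotlib 3.10.9. Probe-level signals, exon-level values and detection calls were not analysed here.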

Results

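Gene expression was measured on 9 arrays from mouse bone marrow cells transduced with 1 of 3 retroviruses, with 3 arrays per group. The empty vector (MIE, which carries green fluorescent protein alone) was the control, and the other vectors carried GATA2 wild type or the GATA2 variant R396Q. GATA2 is a zinc finger transcription factor of blood stem and progenitor cells. Per the labels, the donors were C57BL/6 females aged 8 weeks that had received 5-fluorouracil at 150 mg/kg 6 days before harvest, and the Lin-negative, Sca-positive, Kit-positive cells were infected and then sorted for green fluorescence after 72 h of culture. Each array gave a log2 signal for 21072 transcript clusters, that is, sets of probes summed per gene or locus. The signals are of sorted cells in bulk, so the folds below do not tell changes within cells from changes in the mix of cells. The median log2 signal per array ran from 6.06 (R396Q 3) to 6.19 (wild type 1). Pearson correlations between arrays, taken across clusters that are not independent replicates, were 0.990 to 0.992 within empty vector, 0.989 to 0.993 within wild type and 0.990 to 0.995 within R396Q. Between groups they were 0.983 to 0.992 for empty vector with R396Q, 0.975 to 0.986 for wild type with R396Q and 0.971 to 0.979 for empty vector with wild type. Principal components were taken over 14750 of the 21072 clusters. The first principal component held 48.0% of their variance, with wild type at 47.4 to 52.8, R396Q at -19.1 to -14.3 and empty vector at -35.7 to -32.2.

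**Figure D1:**
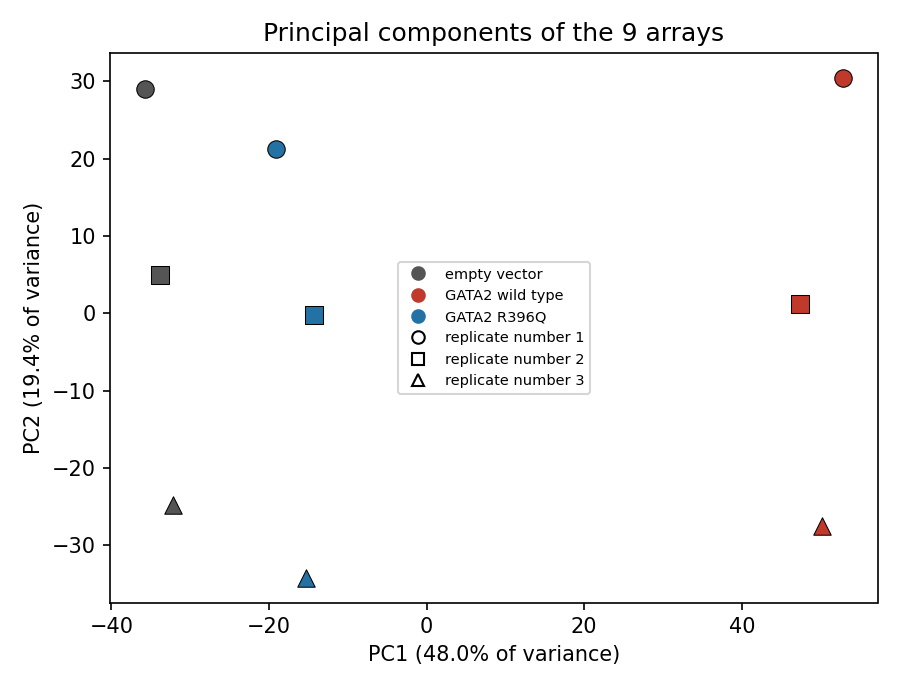
Scores of the 9 arrays on the first principal component (48.0% of the variance) and the second (19.4%), from log2 signals. The components were taken over 14750 of the 21072 clusters. Points are coloured by group and marked by replicate number. Wild type arrays lie at 47.4 to 52.8 on the first axis, apart from R396Q (-19.1 to -14.3) and empty vector (-35.7 to -32.2).

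Every fold below compares means of 3 arrays per group (n = 3), and SE is the standard error of the log2 change from limma. All clusters past the test moved the same way within each of the 3 replicate numbers, that is, 1894 of 1894, 259 of 259 and 1211 of 1211 in the comparisons of wild type with empty vector, R396Q with empty vector and R396Q with wild type. Selection by the test on these same arrays makes this nearly certain, so it is not separate support for the calls. Arrays with the same replicate number deviated from their group means together, so counts with the replicate number as a block are given beside the counts without it. Gene lists were tested with camera at a preset correlation, and none of the list calls in these 3 comparisons held with an estimated correlation (0 in each).

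The comparison of GATA2 wild type with empty vector asked what raised GATA2 did to gene expression in these cells. Red cell and platelet genes were far higher with wild type, and genes of neutrophils and monocytes were far lower. Car1, a carbonic anhydrase of red cell precursors, rose 152-fold (7.25 on the log2 scale, SE 0.36). Klf1, the main transcription factor of the erythroid lineage, rose 26.2-fold (SE 0.40). Clec5a, a receptor of myeloid cells, fell 133-fold (-7.05, SE 0.28), and Cd34, a surface marker of progenitors, fell 24.8-fold (-4.63, SE 0.13). Gata2 itself was 2.81-fold higher (1.49, SE 0.14, 95% confidence interval 1.16 to 1.83), with log2 signals of 11.50, 11.24 and 10.94 on the wild type arrays against 9.87, 9.67 and 9.65 on the empty vector arrays, and passed the limma test (adjusted p = 0.0016).

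In all, 1894 of 21072 clusters changed with wild type, of which 977 rose and 917 fell (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 867 changed more than 2-fold (483 up, 384 down), and the median absolute change was 0.91 on the log2 scale. With the replicate block 3667 changed (1685 up, 1982 down), of which 1848 were among the 1894. The signals of the groups did not overlap in 4769 clusters (22.6%, where chance gives 10% for exchangeable arrays without ties), and 4664 had an unadjusted p under 0.05. With the pairing and ties of these arrays the 10% does not hold, and the other 9 splits of the 6 arrays gave 1.73% to 7.64%. A cluster with 6 distinct values is parted by only 1 of the 10 splits, so a high share in the real split lowers the others. Here and in the comparisons below, the other splits therefore do not give a chance level. After Car1, the largest rises with 1 symbol were those of Aqp1, a water channel of red cells (110-fold, SE 0.54), Ces2g (71.1-fold, SE 0.22), Cldn13 (53.2-fold, SE 0.34), Alox8 (50.9-fold, SE 0.62), the cytokine Il1a (39.0-fold, SE 0.55), the embryonic globin Hbb-y (36.6-fold, SE 0.79) and Alox15 (35.7-fold, SE 0.70). The Cldn13 mean with empty vector (4.04) lay below the lower quartile of every array (4.54 or above), where a signal above background is not shown, so its fold and rank are uncertain. After Clec5a, the largest falls were those of Tgfbi (65.7-fold, SE 0.46), the neutrophil collagenase Mmp8 (65.3-fold, SE 0.35), neutrophil elastase, Elane (52.4-fold, SE 1.34), Trem3 (49.4-fold, SE 0.61) and Tfec (48.3-fold, SE 0.32). The Elane call (limma adjusted p = 0.0450) was lost without any 1 of 8 arrays, that is, all but R396Q 3, with an adjusted p of up to 0.121. Of 74 calls of named genes in this comparison, 61 were kept when any 1 array was left out.

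Clusters that the annotation gives to several genes lie outside the naming rule, and those named here were chosen after their values were seen. A pair of clusters shared by the alpha globin genes Hba-a1 and Hba-a2 rose 914-fold (9.84, SE 0.36) and 443-fold (8.79, SE 0.23) with wild type, from log2 means of 6.84 and 6.43 to 16.7 and 15.2. Their means with R396Q were 7.26 and 6.74, which is 684-fold and 357-fold below wild type. A cluster of the adult beta globin genes was 76.9-fold lower with R396Q than with wild type (SE 0.90). A cluster of the Sprr2a genes rose 249-fold (SE 0.33), and 1 of Wfdc21 fell 83.5-fold (SE 0.65).

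Of 24 measured erythroid genes, 19 rose with wild type, none fell and 5 did not pass the test (21 rose when adjusted over the list alone), with a median change of 2.41 (camera adjusted p = 7e-22, and adjusted p = 0.175 with an estimated correlation). The medians within the 3 replicate numbers were 2.01 to 2.67. Mfsd2b, a lipid transporter of red cells and platelets, rose 15.4-fold (SE 0.15), Car2 18.1-fold (SE 0.22) and Cldn13 as above. Of 20 genes of heme and iron handling, 8 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.44 and 0.36 to 0.66 within numbers (camera adjusted p = 3.48e-05, and adjusted p = 0.280 with an estimated correlation). Cpox and Fech, enzymes of heme synthesis, rose 7.72-fold (SE 0.10) and 2.42-fold (SE 0.15). The porphyrin transporter Abcb6 rose 4.03-fold (SE 0.24). Of 25 megakaryocyte genes, 19 rose and none fell (20 adjusted over the list alone), with a median of 2.31 and 2.24 to 2.32 within numbers (camera adjusted p = 8.76e-18, and adjusted p = 0.0774 with an estimated correlation). Vwf, which tethers platelets to vessel walls, rose by 3.59 on the log2 scale (SE 0.17), Itga2b, a chain of the fibrinogen receptor of platelets, 6.76-fold (SE 0.22), Cd226 8.98-fold (SE 0.30) and Rap1b 1.54-fold (SE 0.05).

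Genes of mast cells and basophils were also higher with wild type. Of 29 mast cell genes, 12 rose and 2 fell (15 and 3 adjusted over the list alone), with a median of 1.43 and 0.90 to 1.64 within numbers (camera adjusted p = 2.26e-06, and adjusted p = 0.357 with an estimated correlation). Hdc, the enzyme that makes histamine, rose 17.7-fold (SE 0.28) and the monoamine transporter Slc18a2 9.90-fold (SE 0.23). Kit, the stem cell factor receptor and also a mast cell gene, fell 7.02-fold (-2.81, SE 0.08). Of 20 basophil and eosinophil genes, 8 rose and none fell (11 and 0 adjusted over the list alone, and 14 and 1 with the block), with a median of 2.70 and 1.44 to 2.95 within numbers (camera adjusted p = 2.29e-10, and adjusted p = 0.280 with an estimated correlation). The cytokine genes Il6, Il13 and Il4 rose 11.3-fold (SE 0.23), 5.37-fold (SE 0.18) and 7.87-fold (SE 0.30), and the receptor gene Cd200r3 rose 14.4-fold (SE 0.38).

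Of 32 genes of neutrophils and their granules, 11 fell and 1 rose with wild type (14 and 1 adjusted over the list alone, and 22 and 1 with the block), with a median of -2.17 and -2.15 to -1.66 within numbers (camera adjusted p = 2.26e-08, and adjusted p = 0.404 with an estimated correlation). Csf3r, the receptor for granulocyte colony-stimulating factor, fell 39.4-fold (SE 0.39), Ms4a3 7.39-fold (SE 0.29) and Cst7 1.60-fold (SE 0.09). Of 36 monocyte and macrophage genes, 18 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -2.34 and -2.54 to -1.22 within numbers (camera adjusted p = 1.48e-09, and adjusted p = 0.357 with an estimated correlation). The mannose receptor gene Mrc1 fell 24.6-fold (SE 0.44), Sirpa 5.19-fold (SE 0.20) and Trem2 1.93-fold (SE 0.07). Of 26 cytokine and growth factor receptors, 12 fell and 4 rose (14 and 5 adjusted over the list alone), with a median of -1.07 and -1.24 to -0.68 within numbers (camera adjusted p = 0.00202, and adjusted p = 0.359 with an estimated correlation). Il6st, the signal chain of the interleukin 6 receptor, fell 8.32-fold (SE 0.28) and Csf2ra 2.78-fold (SE 0.14).

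The 24 stem cell genes split, with 5 that rose and 2 that fell (7 and 2 adjusted over the list alone, and 8 and 3 with the block), a median of 0.08 and a list test not past the threshold (camera adjusted p = 0.159) except without empty vector 2 (median 0.13, adjusted p = 0.0323). Gfi1b, a repressor that erythroid cells and megakaryocytes need, was among those that rose (19.1-fold, SE 0.29), whereas Kit and Cd34 fell. Of 23 blood transcription factors, 9 rose and 5 fell (9 and 6 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.0728). This list passed without empty vector 1 (adjusted p = 0.0301), wild type 2 (0.0314) or wild type 3 (0.0413). Fli1 rose 1.81-fold (SE 0.05) and Zfpm1, the partner of GATA factors, 6.93-fold (SE 0.22). Gata2, the transduced gene, is in this list and counts among those that rose, although its rise may come from the vector.

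Of 23 p53 response genes, 7 rose with wild type and none fell (11 and 0 adjusted over the list alone, and 12 and 1 with the block), with a median of 0.52 and 0.50 to 0.70 within numbers (camera adjusted p = 5.8e-08, and adjusted p = 0.280 with an estimated correlation). Cdkn1a, the p21 inhibitor of the cell cycle, rose 3.07-fold (SE 0.17), Trp53inp1 4.67-fold (SE 0.23) and the DNA polymerase gene Polk 1.42-fold (SE 0.04). Of 23 genes in the list of cell cycle inhibitors and quiescence, 6 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.47 and 0.22 to 0.80 within numbers (camera adjusted p = 0.000537, and adjusted p = 0.382 with an estimated correlation). Gadd45b fell 6.25-fold (SE 0.43). Of 32 S phase genes, 3 fell and none rose, also adjusted over the list alone (6 and 1 with the block), with a median of -0.24 and -0.22 to -0.17 within numbers (camera adjusted p = 0.00983, and adjusted p = 0.357 with an estimated correlation). The helicase Hells fell 2.45-fold (SE 0.08). The others were Cdca7, lost without empty vector 1 or 3 (limma adjusted p up to 0.0601), and Chaf1a, lost with the block (0.0653) and without any 1 of 8 arrays, all but empty vector 3 (up to 0.134). Of 40 genes of G2 and M phase, 3 rose and 1 fell (4 and 1 adjusted over the list alone, and 11 and 3 with the block), with a median of 0.08 and 0.00 to 0.22 within numbers (camera adjusted p = 0.0199, and adjusted p = 0.577 with an estimated correlation). That call was lost without empty vector 2 (adjusted p = 0.364, median -0.02) and without wild type 1 (adjusted p = 0.106), and the median was 0.12 without empty vector 1. Ckap2l rose 2.74-fold (SE 0.16) and Top2a 1.29-fold (SE 0.05), and Bub1 fell 1.45-fold (SE 0.08). Kif11 also rose, a call lost without any 1 empty vector or R396Q array (limma adjusted p up to 0.0930).

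Other lists did not pass the camera test on all 9 arrays with wild type. Of 25 dendritic cell genes 3 rose and 4 fell, also adjusted over the list alone (median -0.26, camera adjusted p = 0.207). Among these Batf3 fell 1.20-fold (SE 0.03) and Id2 rose 5.18-fold (SE 0.40). Zbtb46 rose, lost without any 1 empty vector array, wild type 1 or 2 or R396Q 2 (limma adjusted p up to 0.0715), and Cd86 fell, lost without empty vector 2 or 3, wild type 2 or 3 or R396Q 3 (up to 0.0886). Of 27 lymphoid genes 1 fell and 0 did when adjusted over the list alone, and 3 with the block (median -0.05, camera adjusted p = 0.555). This was Notch1 (-0.30, SE 0.07), whose limma call (adjusted p = 0.0481) was lost without any 1 of 8 arrays, all but wild type 1, with an adjusted p of up to 0.127. Of 22 stress genes 2 rose, also adjusted over the list alone, and 3 rose and 2 fell with the block (median 0.10, camera adjusted p = 0.142), and the list passed without wild type 2 (median 0.21, adjusted p = 0.0431). These were Ddit3 (3.49-fold, SE 0.34) and Asns (1.44-fold, SE 0.13). The Ddit3 call was lost without empty vector 2 or 3 or wild type 1 or 3 (limma adjusted p up to 0.0599), and that of Asns without any 1 of 7 arrays, all but empty vector 2 and 3 (up to 0.137). None of 21 ribosomal protein genes (median -0.01, with the test pointing up, camera adjusted p = 0.949) or of 20 stromal and endothelial genes (median 0.18, camera adjusted p = 0.312) changed, nor did any when adjusted over the list alone, while with the block 1 ribosomal gene, Rps9, fell (limma adjusted p = 0.0258). None of 37 interferon response genes changed without the block, also adjusted over the list alone, with a median of 0.31 and 0.18 to 0.63 within numbers (camera adjusted p = 0.321, and adjusted p = 0.872 with an estimated correlation). With the block 7 rose and 1 fell (camera adjusted p = 0.000334 at the preset correlation alone), and without the block the list passed when empty vector 1 (median 1.42, adjusted p = 0.000997) or wild type 3 (median 1.05, adjusted p = 0.0202) was left out. At an unadjusted p under 0.05 in limma, the ribosomal list had 2 genes, the interferon list 0 and the stromal list 0.

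Some list results with wild type depended on other settings. The G2 and M phase call was lost without the dimmest 30% (camera adjusted p = 0.0744) or 50% of clusters (0.0782), with array weights (0.0576), with at least 6 distinct values and the block (0.0554) and with fry (adjusted p = 0.305). The list of blood transcription factors passed after median subtraction (0.0255) and with fry (0.0169), the stem cell list without the dimmest 50% (median 0.82, 0.0320), and the dendritic cell list with at least 6 distinct values and the block (0.0480). The erythroid median was 3.79 without the dimmest 50%, and that of the G2 and M phase genes 0.05 with array weights.

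Some small counts with wild type include genes outside the naming rule, which were chosen after their values were seen and were not part of the tests that left out arrays. The other mast cell gene that fell was Hpgds (-1.62), the neutrophil gene that rose was the chemokine receptor gene Cxcr2 (1.90), and the monocyte gene that rose was the chemokine gene Ccl6 (6.08-fold). Among the receptors, Epor (2.55), Ptger3 (2.00), Cxcr2 and the angiopoietin receptor gene Tek (1.65) rose. The other stem cell genes that rose were Slamf1 (3.58), Mllt3 (0.78), Tek and Vwf, which is given above with the megakaryocyte genes and stands in both lists. The transcription factor genes that fell were Erg (-1.62), Lyl1 (-3.01), Hhex (-0.23), Irf8 (-2.31) and Gfi1 (-0.78). Alas1 (-1.87), an enzyme that starts heme synthesis outside the erythroid lineage, was the heme gene that fell. The other dendritic cell genes were Ccl17 (0.68), which rose, and Itgax (-0.51) and Flt3 (-2.29), which fell.

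**Figure D2:**
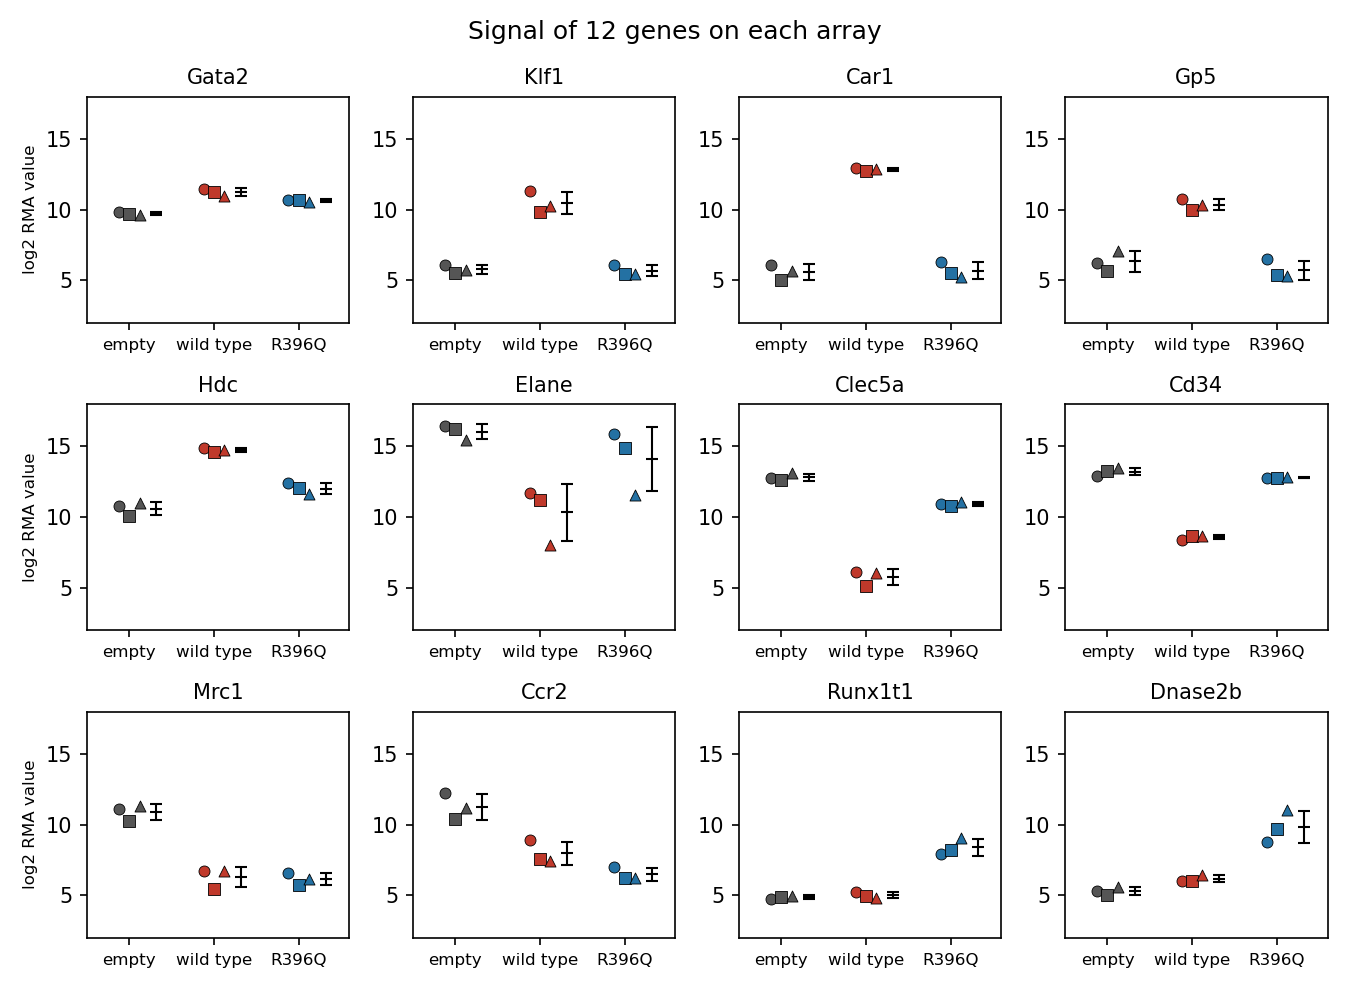
Log2 signal of 12 genes on each of the 9 arrays, by group, with circles, squares and triangles for replicate numbers 1, 2 and 3, and bars for the mean and SD of 3 arrays. Klf1 and Car1 were 26.2-fold and 152-fold higher with wild type than with empty vector, and Mrc1 was 24.6-fold lower with wild type and 26.9-fold lower with R396Q.

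The comparison of R396Q with empty vector asked what the variant form did in the same cells. Monocyte genes were lower with R396Q, as with wild type, while none of the erythroid genes changed. Mrc1 fell 26.9-fold (-4.75, SE 0.44) and Kit 3.50-fold (-1.81, SE 0.08). Tgfbr3, a coreceptor for transforming growth factor beta, rose 20.3-fold (4.35, SE 0.31) and Runx1t1, a transcriptional corepressor, 11.5-fold (3.52, SE 0.28). Gata2 was 1.87-fold higher (0.90, SE 0.14, 95% confidence interval 0.57 to 1.24), with log2 signals of 10.65, 10.72 and 10.53 on the R396Q arrays (limma adjusted p = 0.0394). The Gata2 call was lost without any 1 of 7 arrays, with a limma adjusted p of 0.0689, 0.0845 and 0.113 without empty vector 1, 2 and 3, 0.0799 without wild type 2, and 0.123, 0.155 and 0.101 without R396Q 1, 2 and 3.

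In all, 259 clusters changed with R396Q, of which 139 rose and 120 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 138 of these changed more than 2-fold (75 up, 63 down). With the replicate block 632 changed (349 up, 283 down), of which 226 were among the 259. The groups did not overlap in 2968 clusters (14.1%, where chance gives 10% under the same conditions and the other 9 splits gave 1.89% to 9.72%), and 2540 had an unadjusted p under 0.05. The count of 259 was 165 without wild type 3, and 98, 85 and 109 without R396Q 1, 2 and 3. After Tgfbr3, Nt5e, which makes adenosine, rose 16.2-fold (SE 0.40), the growth factor Hgf 11.7-fold (SE 0.23), Il6 9.29-fold (SE 0.23), P2rx1 8.85-fold (SE 0.29) and Prkca 6.80-fold (SE 0.19). Dnase2b had the largest rise with 1 symbol (23.1-fold, SE 0.53), lost without R396Q 2 (limma adjusted p = 0.0697). Slamf1, a marker of stem cells, rose 9.54-fold (SE 0.41), a call lost without empty vector 1 or 3 or R396Q 1 or 2 (limma adjusted p up to 0.0868). Igfbp5 rose by 3.59 on the log2 scale (SE 0.53), and its call was lost without any 1 of 8 arrays, all but wild type 2 (up to 0.0998). Dse fell 20.3-fold (SE 0.40), the matrix proteoglycan gene Vcan 13.9-fold (SE 0.29), Tfec 10.3-fold (SE 0.32) and the interleukin 6 receptor gene Il6ra 8.99-fold (SE 0.22). Ccr2, the receptor that draws monocytes from the marrow, had the largest fall (27.8-fold, SE 0.57), lost without empty vector 3 or any 1 R396Q array (limma adjusted p up to 0.0796), and the fall of Tgfbi (16.0-fold, SE 0.46) was lost without R396Q 2 or 3 (up to 0.0637). The falls of Dab2 (11.8-fold, SE 0.48), the chemokine Ccl24 (-3.46 on the log2 scale, SE 0.46) and F13a1, a chain of clotting factor XIII (10.5-fold, SE 0.50), were lost without any 1 of 7, 5 and 8 arrays. These were all but empty vector 1 and 3 for Dab2 (limma adjusted p up to 0.0897), empty vector 1, wild type 3 and the R396Q arrays for Ccl24 (up to 0.0897), and all but empty vector 2 for F13a1 (up to 0.126). Of 40 calls of named genes here, 19 were kept when any 1 array was left out.

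Of 36 monocyte and macrophage genes, 8 fell and none rose with R396Q (20 and 2 adjusted over the list alone, and 12 and 0 with the block), with a median of -1.22 and -1.49 to -0.92 within numbers (camera adjusted p = 1.44e-12, and adjusted p = 0.319 with an estimated correlation). Besides Mrc1 and Ccr2 these included Trem2 (2.02-fold, SE 0.07). The Ccr2 call, as given above, was lost without empty vector 3 or any 1 R396Q array. Its signals were 12.2, 10.4 and 11.2 with empty vector and 7.01, 6.24 and 6.21 with R396Q, so no single array made the fall. Of 25 dendritic cell genes, 2 fell and none rose (3 and 0 adjusted over the list alone, and 1 and 0 with the block), with a median of -0.26 and -0.28 to -0.01 within numbers (camera adjusted p = 0.000422, and adjusted p = 0.280 with an estimated correlation). These were Batf3 (1.20-fold, SE 0.03), lost without any 1 R396Q array (limma adjusted p up to 0.0636), and Cd86 (3.53-fold, SE 0.30), lost without any 1 of the 9 arrays (up to 0.152) and with the block (0.0533). Of 26 cytokine and growth factor receptors, 5 fell and 2 rose (10 and 5 adjusted over the list alone), with a median of -0.49 and -0.73 to -0.27 within numbers (camera adjusted p = 0.0177, and adjusted p = 0.416 with an estimated correlation), and the median was -0.23 without empty vector 3 and -0.25 without R396Q 2. Kit and Il6ra were among those that fell, with Il6st (-2.39), lost without empty vector 1 or any 1 R396Q array (limma adjusted p up to 0.0771), Ccr2 and Csf2ra (-1.04), the last chosen after its values were seen. Those that rose were Ptger3 (1.79), lost without R396Q 2 (limma adjusted p = 0.0616), and Cxcr2, lost without any 1 of 7 arrays, all but empty vector 1 and 3 (up to 0.163).

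Of 24 erythroid genes none changed with R396Q, also adjusted over the list alone, with a median of -0.01, a test that pointed up, and -0.19 to 0.07 within numbers (camera adjusted p = 0.793). Fech differed by 0.37 (SE 0.15) and Slc25a37 by -0.45 (SE 0.17). None of 20 heme and iron genes changed (0 rose and 4 fell adjusted over the list alone, and 1 fell with the block, namely Alas1 at a limma adjusted p of 0.0361), but the list was lower, with a median of -0.18 and -0.30 to -0.11 within numbers (camera adjusted p = 0.0119, and adjusted p = 0.382 with an estimated correlation). The median was -0.11 without empty vector 3, -0.12 without R396Q 2 and -0.31 without R396Q 3. The Cpox difference was -0.58 (SE 0.10, limma adjusted p = 0.0503). Of 25 megakaryocyte genes 1 rose (6 adjusted over the list alone, and 5 with the block), with a median of 0.20 and 0.06 to 0.37 within numbers (camera adjusted p = 0.00267, and adjusted p = 0.357 with an estimated correlation). The median was -0.02 without empty vector 3, 0.03 without R396Q 1 and -0.08 without R396Q 2, while the test still pointed up. This was Rap1b (1.22-fold, SE 0.05), lost without any 1 of 8 arrays, all but empty vector 3 (limma adjusted p up to 0.163). Itga2b differed by 1.23 (SE 0.22, limma adjusted p = 0.0606, and 0.0358 with the block).

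Of 29 mast cell genes 1 rose and 1 fell with R396Q (8 and 2 adjusted over the list alone, and 5 and 1 with the block), with a median of 0.35 and 0.08 to 0.60 within numbers (camera adjusted p = 0.00833, and adjusted p = 0.533 with an estimated correlation). The list call was lost without empty vector 2 (median 0.13, adjusted p = 0.134). The gene that fell was Kit, and the gene that rose was Ltc4s, which makes leukotrienes (1.52-fold, SE 0.07), from a mean (4.30) below the lower quartile of every array, so that its fold is uncertain, and a call lost without empty vector 1 or 3 or any 1 R396Q array (limma adjusted p up to 0.0657). Of 20 basophil and eosinophil genes 1 rose and none fell (3 and 0 adjusted over the list alone, and 2 and 0 with the block), with a median of 0.33 and 0.14 to 0.90 within numbers (camera adjusted p = 0.00104, and adjusted p = 0.416 with an estimated correlation). The median was 0.60 without empty vector 1, 0.18 without empty vector 2 and 0.73 without R396Q 3. This was Il6, and Alox15 differed by 4.05 (SE 0.70, limma adjusted p = 0.0511, and 0.0148 with the block). Of 23 blood transcription factors 3 rose and 1 fell (7 and 3 adjusted over the list alone), with a median of 0.17 and 0.13 to 0.18 within numbers (camera adjusted p = 0.00669, and adjusted p = 0.404 with an estimated correlation). The median was 0.26 without R396Q 3. Fli1 rose 1.47-fold (SE 0.05) and Gata2 as above. Since Gata2 is the transduced gene, its rise may come from the vector and is no evidence of a response of the list, whose test includes it. Runx1 rose 2.19-fold (SE 0.17), a call lost without any 1 of 8 arrays, all but wild type 3 (limma adjusted p up to 0.143). Lyl1 fell 4.58-fold (SE 0.36), lost with the block (limma adjusted p = 0.0605) and without any 1 of 8 arrays, all but R396Q 1 (up to 0.173).

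None of 40 genes of G2 and M phase changed with R396Q (3 rose adjusted over the list alone, and 1 fell with the block), while the list was higher, with a median of 0.16 and 0.06 to 0.23 within numbers (camera adjusted p = 4.44e-05, and adjusted p = 0.382 with an estimated correlation). The median was 0.08 without empty vector 2. Top2a, the topoisomerase of dividing cells, differed by 0.30 (SE 0.05, limma adjusted p = 0.0537). None of 21 ribosomal protein genes changed, also adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.00815, and adjusted p = 0.498 with an estimated correlation). That list call was lost without empty vector 2 (median 0.02, adjusted p = 0.214), the medians within numbers ran from 0.00 to 0.13 with number 1 below 0, and under quantile normalization the direction flipped. Of 32 neutrophil genes 2 rose and 1 fell (3 and 3 adjusted over the list alone, and also with the block), with a median of -0.49, and the list did not pass (camera adjusted p = 0.321) except without empty vector 3 (median -0.96, adjusted p = 0.00975) or R396Q 1 (median -0.84, adjusted p = 0.0205). Cst7, which had fallen with wild type, rose 2.37-fold (SE 0.09). Cxcr2 rose 4.21-fold (SE 0.33), lost without any 1 of 7 arrays, all but empty vector 1 and 3 (limma adjusted p up to 0.163), and Mmp8 fell 5.26-fold (SE 0.35), lost without any 1 of 8, all but empty vector 2 (up to 0.0977).

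Other lists did not pass the camera test on all 9 arrays with R396Q. Of 24 stem cell genes Slamf1 rose and Kit fell (2 and 1 adjusted over the list alone, median -0.09, camera adjusted p = 0.766). Of 32 S phase genes only Tyms rose, also adjusted over the list alone (1.68-fold, SE 0.09, list median -0.04, camera adjusted p = 0.709), and without any 1 R396Q array its call was lost (limma adjusted p up to 0.0819). None of 27 lymphoid genes changed (1 rose adjusted over the list alone, median 0.05, camera adjusted p = 0.361), although the list passed without R396Q 3 (median 0.07, adjusted p = 0.0316). None of the cell cycle inhibitor and quiescence genes (median 0.01 and mean -0.03, camera adjusted p = 0.525), p53 response genes (median 0.02, camera adjusted p = 0.387), stress genes (median -0.03, camera adjusted p = 0.647) or stromal and endothelial genes (median 0.05, camera adjusted p = 0.683) changed, also adjusted over the list alone. None of 37 interferon response genes changed, also adjusted over the list alone, with a median of -0.29 and -0.63 to -0.17 within numbers (camera adjusted p = 0.387, and adjusted p = 0.881 with an estimated correlation). With the block and the preset correlation its camera adjusted p was 0.000668. The interferon list also passed without empty vector 3 (median -0.93, adjusted p = 0.0164) and without R396Q 1 (median -1.28, adjusted p = 0.00231). At an unadjusted p under 0.05 in limma, the lists with no changed gene had 2 erythroid, 7 heme and iron, 7 G2 and M phase, 2 ribosomal, 2 lymphoid, 2 cell cycle inhibitor, 3 p53 response, 3 stress, 1 stromal and 0 interferon genes.

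Some list results with R396Q depended on other settings. The call of the blood transcription factors was lost with quantile normalization (camera adjusted p = 0.0990) and with fry (adjusted p = 0.0871), and that of the mast cell genes without the dimmest 30% (0.0578) or 50% of clusters (0.0518) and with fry (0.562). The ribosomal call was lost without the dimmest 30% (0.0795) or 50% (0.272), with at least 6 distinct values without the block (0.114) and with it (0.108), and with fry (0.284). Calls of the megakaryocyte (0.123), basophil and eosinophil (0.161), G2 and M phase (0.166) and heme and iron lists (0.0613) were lost with fry. The neutrophil list passed after median subtraction (0.0359) and quantile normalization (0.0385), and the S phase list after quantile normalization (median -0.11, 0.0158). The megakaryocyte median was 0.06 with quantile normalization, and that of the dendritic cell genes -0.49 without the dimmest 50% and -0.40 with at least 6 distinct values.

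**Figure D3:**
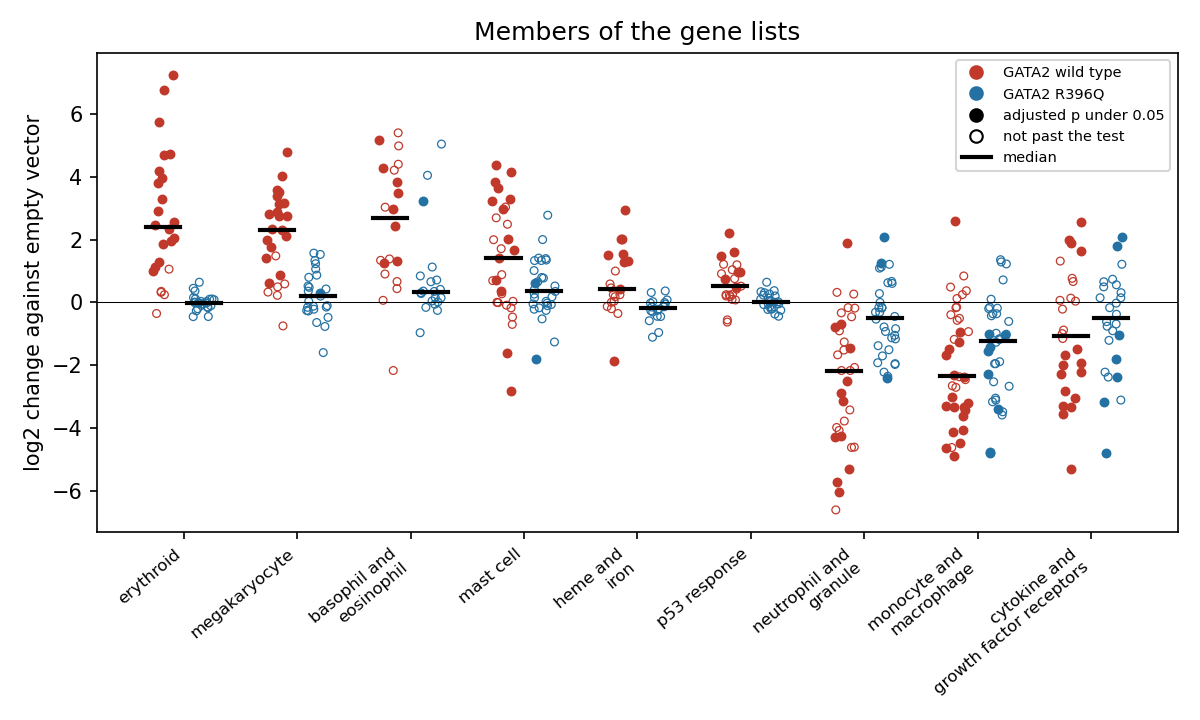
Log2 change of the members of 9 gene lists against empty vector, for wild type (red) and R396Q (blue), with filled points for adjusted p under 0.05 and a bar at each list's median. The erythroid median was 2.41 with wild type and -0.01 with R396Q, and the monocyte medians were -2.34 and -1.22.

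The comparison of R396Q with wild type tested directly where the variant differed from the normal protein. Erythroid and megakaryocyte genes were far lower with R396Q than with wild type, and neutrophil genes were higher. Car1 was 143-fold lower (-7.16, SE 0.36), Klf1 28.1-fold lower (SE 0.40) and the platelet glycoprotein gene Gp5 25.1-fold lower (SE 0.46). Cd34 was 18.6-fold higher (4.22, SE 0.13) and Kit 2.00-fold higher (1.00, SE 0.08). The Gata2 signal differed by -0.59 (SE 0.14, 95% confidence interval -0.92 to -0.26) and did not pass the limma test (adjusted p = 0.0633), although it did with the block (0.0222) and without wild type 3 (-0.73, 0.0235).

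In all, 1211 clusters differed between R396Q and wild type, 563 higher and 648 lower with R396Q (limma, Benjamini-Hochberg adjusted p under 0.05), and 573 differed more than 2-fold (236 up, 337 down). With the replicate block 2750 differed (1497 up, 1253 down), of which 1182 were among the 1211. The groups did not overlap in 4347 clusters (20.6%, where chance gives 10% under the same conditions and the other 9 splits gave 1.35% to 7.65%), and 3720 had an unadjusted p under 0.05. The count of 1211 was 650, 702 and 788 without R396Q 1, 2 and 3. The largest rises included Adgrl4 (52.0-fold, SE 0.62), Clec5a (35.4-fold, SE 0.28), Laptm4b (31.6-fold, SE 0.22), Parp8 (29.5-fold, SE 0.24), the proton-sensing receptor gene Gpr65 (26.1-fold, SE 0.33), Trem3 (17.8-fold, SE 0.61) and Trem1 (17.3-fold, SE 0.29). Stfa1 rose 35.3-fold (SE 0.86), a call lost without wild type 1 or any 1 R396Q array (limma adjusted p up to 0.0688). The largest falls after Car1 included Ces2g (97.8-fold, SE 0.22), Aqp1 (70.3-fold, SE 0.54), Cldn13 (58.8-fold, SE 0.34), Il1a (35.6-fold, SE 0.55) and the amino acid transporter Slc38a5 (30.7-fold, SE 0.69). The Cldn13 mean with R396Q (3.90) again lay below the lower quartile of every array, so its fold and rank are uncertain here too. Ppbp, a platelet chemokine, fell 46.6-fold (SE 1.00), lost without any 1 wild type array or R396Q 2 (limma adjusted p up to 0.0804), and Hbb-y 34.1-fold (SE 0.79), lost without R396Q 1 or 2 (up to 0.0569). A 3-group test of any difference gave 1752 clusters (limma, adjusted p under 0.05), 3608 with the block, and 1107 without wild type 1, 1164 without wild type 3 and 1155 without R396Q 2. Of 68 calls of named genes in the comparison of R396Q with wild type, 49 were kept when any 1 array was left out.

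Of 24 erythroid genes, 19 were lower with R396Q than with wild type and none was higher (21 adjusted over the list alone), with a median of -2.38 and -2.76 to -2.10 within numbers (camera adjusted p = 3.01e-26, and adjusted p = 0.143 with an estimated correlation). Mfsd2b was 15.1-fold lower (SE 0.15) and Car2 13.3-fold lower (SE 0.22). Of 20 heme and iron genes, 7 were lower and none higher (13 and 0 adjusted over the list alone, and 10 and 1 with the block), with a median of -0.73 and -0.76 to -0.60 within numbers (camera adjusted p = 6.03e-10, and adjusted p = 0.143 with an estimated correlation). Cpox was 11.6-fold lower (SE 0.10) and Steap3, an iron reductase, 3.54-fold lower (SE 0.20). Of 25 megakaryocyte genes, 13 were lower and none higher (18 adjusted over the list alone), with a median of -1.52 and -1.51 to -1.42 within numbers (camera adjusted p = 9.33e-16, and adjusted p = 0.0774 with an estimated correlation). Vwf was 13.4-fold lower (SE 0.17) and Cd226 8.75-fold lower (SE 0.30).

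Of 29 mast cell genes, 8 were lower and 2 higher with R396Q than with wild type (10 and 2 adjusted over the list alone), with a median of -0.45 and -1.21 to -0.05 within numbers (camera adjusted p = 0.000537, and adjusted p = 0.416 with an estimated correlation). The median was -0.14 without wild type 1. Hdc was 6.65-fold lower (SE 0.28) and Cd200r3 17.2-fold lower (SE 0.38). Of 20 basophil and eosinophil genes, 5 were lower and none higher (7 and 1 adjusted over the list alone, and 9 and 1 with the block), with a median of -1.07 and -1.44 to -0.78 within numbers (camera adjusted p = 6.45e-07, and adjusted p = 0.355 with an estimated correlation). The median was -1.68 without wild type 3. Il13 was 4.41-fold lower (SE 0.18) and Itga2 14.7-fold lower (SE 0.44). Of 32 neutrophil genes, 6 were higher and none lower (11 adjusted over the list alone, and 16 with the block), with a median of 1.96 and 1.60 to 1.94 within numbers (camera adjusted p = 1.71e-09, and adjusted p = 0.382 with an estimated correlation). Mmp8 was 12.4-fold higher (SE 0.35), Ms4a3 7.39-fold higher (SE 0.29), Csf3r 8.46-fold higher (SE 0.39) and Cst7 3.80-fold higher (SE 0.09). Of 36 monocyte genes 4 were higher and 1 lower, also adjusted over the list alone, and 6 and 2 with the block (median 0.20, camera adjusted p = 0.321). Those higher were Fcgr2b, lost without R396Q 1 or 2 (limma adjusted p up to 0.0530), the lysozyme gene Lyz2, lost without any 1 wild type array or R396Q 1 or 3 (up to 0.0809), Lyz1, lost without any 1 of 7 arrays, all but empty vector 2 and 3 (up to 0.128), and Sirpa (0.94). Cx3cr1 was lower, lost without empty vector 1, wild type 1 or 2 or any 1 R396Q array (limma adjusted p up to 0.0925). Ltc4s (0.61, from a wild type mean of 4.29, below the lower quartile of every array, so uncertain in size) was the mast cell gene that was higher besides Kit, and Ccl4 (-1.22) and Il4 (-2.26) were the other basophil and eosinophil genes that were lower. Sirpa, Ltc4s and Ccl4 were chosen after their values were seen.

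Of 23 p53 response genes, 7 were lower with R396Q than with wild type and none higher (11 adjusted over the list alone, and 14 and 1 with the block), with a median of -0.57 and -0.59 to -0.40 within numbers (camera adjusted p = 1.23e-08, and adjusted p = 0.280 with an estimated correlation). Trp53inp1 was 4.35-fold lower (SE 0.23). Of 23 genes in the list of cell cycle inhibitors and quiescence, 3 were lower (6 lower and 1 higher adjusted over the list alone, and 5 and 2 with the block), with a median of -0.44 and -0.74 to -0.17 within numbers (camera adjusted p = 0.000664, and adjusted p = 0.382 with an estimated correlation). Among them Cdkn1a was 1.97-fold lower (SE 0.17), a call lost without wild type 1 or 3 or any 1 R396Q array (limma adjusted p up to 0.0844). The others were Gadd45g, lost without any 1 of 7 arrays, all but wild type 1 and 2 (up to 0.124), and Btg2, lost without any 1 of 8, all but wild type 2 (up to 0.153). Of 32 S phase genes 3 were higher, also adjusted over the list alone, and 5 with the block, with a median of 0.18 and 0.13 to 0.18 within numbers (camera adjusted p = 0.00169, and adjusted p = 0.307 with an estimated correlation). The median was 0.11 without wild type 2. Hells was 1.92-fold higher (SE 0.08). Tyms and Cdca7 were the others, each lost without any 1 of 7 arrays, all but empty vector 1 and 3 for Tyms (limma adjusted p up to 0.121) and all but wild type 1 and 3 for Cdca7 (up to 0.147). Of 22 stress genes 1 was lower, also adjusted over the list alone, and 2 with the block (median -0.15, camera adjusted p = 0.0267, and adjusted p = 0.494 with an estimated correlation), a list call lost without wild type 1 (median -0.08, adjusted p = 0.307) and R396Q 1 (adjusted p = 0.0587). The median was -0.25 without wild type 2 and -0.22 without R396Q 2. This was Ddit3 (3.99-fold, SE 0.34), lost without wild type 1 or 3 or any 1 R396Q array (limma adjusted p up to 0.0725).

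Of 26 cytokine and growth factor receptors, 4 were higher and 2 lower with R396Q than with wild type (6 and 2 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 0.0199, and adjusted p = 0.416 with an estimated correlation). The list call was lost with the block (adjusted p = 0.0796) and without wild type 2 (0.0731), wild type 3 (0.0695) or R396Q 1 (0.0579). Epor, the erythropoietin receptor gene, was 6.59-fold lower (SE 0.25) and Tgfbr1 1.64-fold higher (SE 0.10). Tnfrsf1a (1.54) was higher and Il6ra (-1.18) lower, each chosen after its values were seen. None of 21 ribosomal protein genes differed, also adjusted over the list alone (median 0.09, camera adjusted p = 0.0211, and adjusted p = 0.552 with an estimated correlation), and the list call was lost without R396Q 2 (adjusted p = 0.0554). None of 37 interferon response genes differed, also adjusted over the list alone, with a median of -0.89 and -1.03 to -0.39 within numbers (camera adjusted p = 0.0616, and adjusted p = 0.872 with an estimated correlation). With the block 13 were lower (camera adjusted p = 6.01e-10 at the preset correlation alone), and without the block the list passed when empty vector 1 (0.0296), wild type 2 (median -1.30, 0.0210), wild type 3 (median -1.50, 0.00116) or R396Q 1 (median -1.69, 0.000156) was left out. The lists of stem cell genes (2 higher and 4 lower of 24, also adjusted over the list alone, median -0.11, camera adjusted p = 0.129) and blood transcription factors (3 and 6 of 23, with 4 and 7 adjusted over the list alone, median -0.07, camera adjusted p = 0.312) did not pass. Erg, a transcription factor of stem cells, was 4.62-fold higher (SE 0.15) and Hhex 1.33-fold higher (SE 0.04). Etv6 (1.05) was higher, and Mllt3 (-0.53) and Meis1 (-1.26) were lower, all chosen after their values were seen. Dendritic cell genes (0 higher and 3 lower of 25, median -0.04, camera adjusted p = 0.207), lymphoid genes (1 and 0 of 27, median 0.07, camera adjusted p = 0.126), G2 and M phase genes (0 and 1 of 40, median 0.04, camera adjusted p = 0.550) and stromal genes (0 and 0 of 20, median -0.06, camera adjusted p = 0.396) did not pass as lists on all 9 arrays either, with the same counts adjusted over the list alone. The lymphoid list passed without wild type 1 (median 0.23, adjusted p = 0.0109) or R396Q 3 (median 0.19, adjusted p = 0.0109), and the dendritic cell list without R396Q 1 (median -0.07, adjusted p = 0.0377). With the block 2 lymphoid genes were higher and 1 lower, and 3 G2 and M phase genes were higher and 2 lower. The ribosomal, interferon and stromal lists had 2, 0 and 0 genes at an unadjusted p under 0.05 in limma.

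The dendritic cell genes lower with R396Q than with wild type were Zbtb46, lost without R396Q 2 (limma adjusted p = 0.0511), Id2 (5.99-fold, SE 0.40), lost without R396Q 1 (0.0530), and Ccl17, lost without wild type 1 or R396Q 1 or 3 (up to 0.0653). The lymphoid gene that was higher was Thy1, lost without any 1 wild type or R396Q array (limma adjusted p up to 0.0998), and the G2 and M phase gene that was lower was Ckap2l (2.11-fold, SE 0.16).

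Some list results between R396Q and wild type depended on other settings. The ribosomal call was lost with quantile normalization (median 0.04, camera adjusted p = 0.600), without the dimmest 30% (0.0972) or 50% of clusters (0.303), with at least 6 distinct values without the block (0.0877) and with it (0.0875), and with fry (adjusted p = 0.218). The S phase call was lost with quantile normalization (median 0.12, 0.120) and without the dimmest 50% (0.0554). The receptor call was lost without the dimmest 30% (0.0670) or 50% (0.147), after median subtraction (0.140) and with at least 6 distinct values and the block (0.0950). The stress call was lost without the dimmest 30% (0.0541) or 50% (0.0600) and with fry (0.166), and the mast cell (0.0533) and cell cycle inhibitor calls (0.0647) with fry. The interferon list passed after median subtraction (0.000798), with quantile normalization (0.0289) and without the dimmest 50% (0.0264), and the stem cell list after median subtraction (0.0262). Without the dimmest 50% the median of the erythroid genes was -3.73, that of the mast cell genes -0.87 (-0.70 without the dimmest 30%) and that of the stress genes -0.44. After median subtraction the stress median was -0.09 and the ribosomal median 0.14.

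The changes that wild type and R396Q made against the same empty vector arrays were also set side by side. Of 977 clusters that rose with wild type and 139 that rose with R396Q, 74 were shared, against 6.44 for independent sets, and of 917 and 120 that fell, 107 were shared, against 5.22. Mrc1, Kit and Trem2 fell with each form, and Il6 and Fli1 rose with each. None rose with wild type and fell with R396Q (5.56 for independent sets), and 14 fell with wild type and rose with R396Q (6.05). Cst7 was among the 14, and so was Cd48 (2.23-fold lower with wild type and 2.83-fold higher with R396Q), chosen after its values were seen. Because both comparisons use the same 3 control arrays, part of this excess may come from them, and 3 control arrays cannot be divided into separate sets of at least 2. The covariance of the log2 changes across clusters was 0.106, against a mean of 0.0265 (SD 0.00167) over 100 simulations in which the groups shared controls and nothing else, which leaves 0.0792 (jackknife standard error 0.0143). Across clusters, which are not independent replicates, Pearson's r was 0.517 against 0.501 (SD 0.0222) in the simulations, a difference of less than 1 SD, and Spearman's rho 0.476 against 0.444 (SD 0.00659). The simulated groups held no effects, so shared controls alone set the simulated values. In the data, effects that only 1 form has would lower r and rho. Their closeness to the simulations therefore does not argue against a shared effect.

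Of the 977 clusters that rose with wild type, 558 were lower with R396Q than with wild type, and of the 917 that fell, 376 were higher. These pairs of comparisons share the wild type arrays, so their overlap is raised by construction, and independent sets would give 30.04 and 24.50. R396Q lay above both other groups in 57 clusters and below both in 9, against 3.71 and 3.69 for independent sets. These comparisons share the R396Q arrays, which also raises their overlap by construction. Those above both included Dnase2b, Nt5e, Runx1t1, Mex3b (6.02-fold above empty vector, SE 0.19) and Adam23 (5.63-fold, SE 0.17), and those below both included Il6ra. Dnase2b no longer passed against empty vector without R396Q 2 (limma adjusted p = 0.0697).

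**Figure D4:**
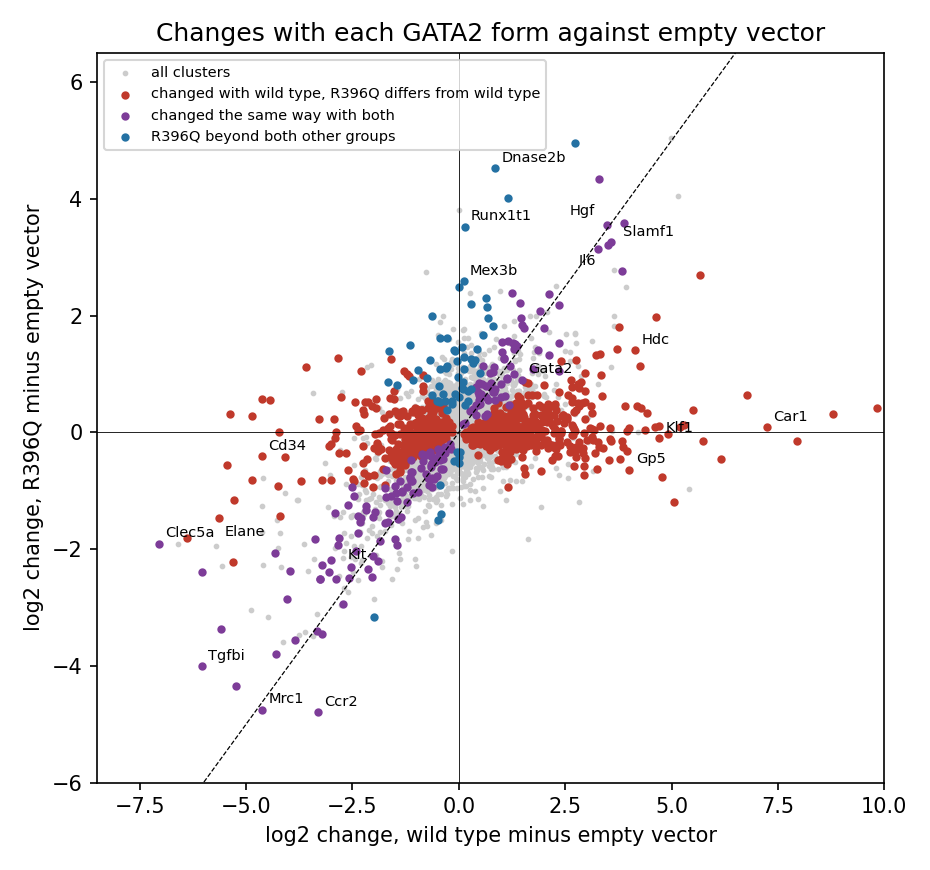
Log2 change with wild type (horizontal) and with R396Q (vertical) against empty vector for each cluster, with a dashed line where they are equal. Red marks clusters that changed with wild type and differed between the forms, but did not pass between R396Q and empty vector. Purple marks those that changed the same way with both, and blue those with R396Q beyond both other groups (57 above, 9 below). Any of the 74 up and 107 down with both forms that also lay beyond both groups are drawn in blue.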

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

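The settings that leave out clusters with fewer than 6 distinct values were chosen only after the data were seen, and the others were planned. With the replicate block 3667, 632 and 2750 clusters changed for wild type with empty vector, R396Q with empty vector and R396Q with wild type, and 3608 in the 3-group test, and the shared covariance was 0.0955. Fits on only the groups compared gave 1026, 94 and 772, where fewer arrays inform the spread. At least 6 distinct values together with the block gave 4220, 1114, 3252 and 4361, and a shared covariance of 0.120. At least 6 distinct values alone gave a shared covariance of 0.100, and leaving out the dimmest 30% or 50% gave 0.111 and 0.142. The Gata2 difference of R396Q from wild type, not past the limma test as deposited, passed with the block (-0.59, adjusted p = 0.0222), at least 6 distinct values (-0.59, 0.0405), these together (-0.59, 0.00957), without the dimmest 30% (-0.59, 0.0415) or 50% (-0.59, 0.0365), after median subtraction (-0.54, 0.0450) or quantile normalization (-0.63, 0.0498) and with array weights (-0.55, 0.0487). Some of these settings test fewer clusters, which can lighten the adjustment. With 1 cluster per symbol, which also tests fewer, the difference did not pass (-0.59, limma adjusted p = 0.0611). The cause was not tested for any of these settings. With an estimated correlation 0, 0 and 0 lists were called, and fry called 3 for R396Q with empty vector. The ribosomal list of R396Q with empty vector reversed under quantile normalization (-0.00204, adjusted p = 0.162), and the cause was not tested. Leaving out 1 array gave 1285 to 1724, 85 to 304 and 650 to 1153 changed clusters and 1107 to 1661 in the 3-group test. It gave a Gata2 change of 1.36 to 1.63, 0.86 to 0.97 and -0.73 to -0.45, a shared covariance of 0.0719 to 0.0862, and 11 to 14, 8 to 12 and 11 to 13 lists called. Of 182 calls of named genes, the block kept 179, quantile normalization 175, the 30% filter 177 of 179 and fits on only the groups compared 133, and 1366 of 1638 values held when 1 array was left out. Of 34 list calls, the block kept 33, trend and robust options 34 and fry 22, and 296 of 306 values held when 1 array was left out. The block ended no call of a named gene or list other than those given beside the result and Chaf1a with wild type (adjusted p = 0.0653). Signal over background could not be assessed, since background values are not given in the sources used here.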

Other observations

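The splits of the samples were planned, except for those within replicate numbers, which, like the families of genes, the comparisons of replicate numbers and the tests of explanations below, were chosen only after the results were seen. Families of genes that share a symbol stem were also tested (18 families, 54 tests with camera, none of which passed with an estimated correlation). Some of their genes are list members too, among them Alox5, Alox12, Alox15, Itga2, Itga2b, Itgb3 and Clec7a. The family results therefore partly restate those of the lists. Of 8 arachidonate lipoxygenase genes, 5 rose with wild type, namely Alox8, Alox15, Alox12, Alox5 and Alox12e, with a median of 2.32 (camera adjusted p = 6.89e-05, and adjusted p = 0.177 with an estimated correlation), and 3 were lower with R396Q than with wild type (camera adjusted p = 0.000696, and adjusted p = 0.177 with an estimated correlation). Of 12 Toll-like receptor genes, Tlr8, Tlr4 and Tlr9 fell with wild type (median -0.76, camera adjusted p = 0.000696, and adjusted p = 0.357 with an estimated correlation), and Tlr8 fell with R396Q (family median -0.95, camera adjusted p = 0.00142, and adjusted p = 0.390 with an estimated correlation). Of 33 C-type lectin genes 10 fell with wild type and none rose, among them Clec4a2, Clec12a and Clec7a (camera adjusted p = 0.0157, and adjusted p = 0.331 with an estimated correlation). Of 23 integrin genes 5 rose with wild type, namely Itga2, Itgb3, Itga2b, Itgb7 and Itga6, and Itgb5 fell (camera adjusted p = 0.0168, and adjusted p = 0.251 with an estimated correlation). None of 33 Hox genes changed with wild type (camera adjusted p = 0.875). These directions were the same after median subtraction and quantile normalization.

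Arrays with the same replicate number also differed from the others across groups. With the group as a term, 1474 clusters differed among the 3 numbers (limma, adjusted p under 0.05). The 37 interferon response genes were higher on the arrays numbered 1, with 32 that rose and a median of 2.74 (camera adjusted p = 1.68e-43, and adjusted p = 0.135 with an estimated correlation), among them Usp18 (5.47, limma adjusted p = 0.00367) and Isg15 (4.06). Neutrophil genes were lower on the arrays numbered 3, with 9 of 32 that fell and a median of -1.24 (camera adjusted p = 4.2e-14, and adjusted p = 0.0269 with an estimated correlation), among them S100a8 (-4.92, limma adjusted p = 0.00627), S100a9 (-4.52, limma adjusted p = 0.00432) and Ngp (-5.78, limma adjusted p = 0.00592). They were higher on number 1 against the mean of 2 and 3, with 7 that rose and a median of 1.25 (camera adjusted p = 1.24e-13, and adjusted p = 0.0269 with an estimated correlation), and on number 2 the median was 0.11 (camera adjusted p = 0.0685). The 3 contrasts share arrays, so the low number 3 arrays enter the rise on number 1, as with S100a8, whose signals with empty vector were 16.6, 16.1 and 12.1 for numbers 1, 2 and 3. At the preset correlation 12, 6 and 8 lists passed the camera test for numbers 1, 2 and 3, and with an estimated correlation only the neutrophil list did, for 1 and 3. For number 1 the lists also higher were basophil and eosinophil (median 0.55), monocyte (0.40), stromal and endothelial (0.24), cell cycle inhibitor (0.22), blood transcription factor (0.21), lymphoid (0.20), erythroid (0.20), receptor (0.15) and G2 and M phase genes (0.09), and the p53 response list was lower (-0.12).

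The erythroid genes were higher with wild type and not with R396Q, while the Gata2 signal with R396Q was also lower, by 0.59, so a lower level of the transcript is a candidate explanation. A log2 response in proportion to the Gata2 signal (0.605 of the wild type change) is argued against for the erythroid genes. Over the 19 erythroid genes that rose with wild type the median ratio was 0.00727 (95% bootstrap interval -0.0252 to 0.0349). By array, erythroid medians against the empty vector mean were 1.96 to 2.69 with wild type and -0.08 to 0.06 with R396Q. Although the signal may read the endogenous gene alone, proportion to any level on the log2 scale needs 1 ratio for all genes. That of the monocyte genes was 0.869 (0.704 to 0.946). The other lists compared ran from -0.0687 (heme and iron) to 0.412 (mast cell). The intervals of the mast cell (0.176 to 0.709) and basophil and eosinophil genes (0.0375 to 0.785) held 0.605. Proportion on a linear scale was not tested. All these intervals come from draws of genes, which are not independent, and hold no spread between arrays, and 0.605 is given without its error. A response that begins only above a threshold of Gata2 stays open, since the wild type array with the lowest Gata2 (10.9) had an erythroid median 2.47 above empty vector and no R396Q array reached that signal (highest 10.7). Normalization between arrays as the whole cause is argued against, since it moves clusters of equal signal alike, while 1000 lists of other clusters matched by signal had median changes of at most 0.243 against 2.41, and rescalings that changed other list calls left a median of 2.39 or above. A changed function of the R396Q protein remains a hypothesis that was not tested. Protein levels, the mix of cell types on each array and whether the probes read the transduced cDNA are not given in the sources used here.

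R396Q lay beyond both other groups in 66 clusters (204 with the block), although the Gata2 signal of its arrays lay between theirs. A response that only rises or only falls with the measured Gata2 level is argued against, since such a response leaves none truly beyond both, and 50 simulations of a scaled response gave a median of 2 and at most 6. This rests on Gata2 having been lower with R396Q than with wild type, which passed the limma test only under some settings, and on the signal standing for the level of the transduced gene, since it may read the endogenous gene alone. A qualitatively different action of the variant on genes such as Runx1t1 and Nt5e remains a hypothesis that was not tested. The pattern it rests on was found and compared with the simulations on the same data.

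The interferon list's median on number 1 exceeded the higher of the other numbers by 3.31 with empty vector, 3.34 with wild type and 2.71 with R396Q. Brighter signal of these arrays as a whole is argued against, since it moves clusters of equal signal alike, while 1000 lists of other clusters matched by signal differed by a median of at most 0.153 against 2.74 for the interferon genes. A condition shared by these arrays, such as a day of culture or infection, may be the source and stays open, since the differences above restate the pattern and no independent test of it was made. What the numbers stand for is not given in the sources used here, so the condition cannot be named.

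Splits of the arrays into other groups were compared with the real ones. For 3 against 3 arrays 10 splits exist, which cannot give a share under 0.05. The real split gave 1894, 259 and 1211 clusters for wild type with empty vector, R396Q with empty vector and R396Q with wild type, and the highest other split gave 0 in each, so that 1 of 10 reached the real count in each, also among the 4 splits that part all 3 same-number pairs. For list calls the real splits gave 12, 10 and 12 and the highest others 13, 10 and 12, and 2 of 10 splits reached the real count in each comparison. In the 3-group test 1 of 100 drawn splits, the real one, reached 1752 clusters, and the highest other gave 867. These splits ignore the pairing by number. Among all 36 splits that keep 1 array of each number in each group, with the replicate block, only the real one reached 3608 clusters. The highest other gave 1168. These 36 splits were chosen after the results were seen and cannot give a share below 1 of 36. Chance was therefore made unlikely for the 3-group test but not excluded. The replicate numbers taken as groups gave 213 in the 3-group test without the block, where the real groups gave 1752.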
